A study of Zea mays with 24 samples.

How the data were processed

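The deposited table holds the signal intensity of 17734 probe sets of an Affymetrix maize genome array on each of 24 arrays, hybridised with biotin-labelled RNA from seedling shoots of the inbred lines Han21 and Ye478. The labels name shoot tissue, while the extraction protocol speaks of mesocotyls. The submitters' processing notes name GCOS and MAS5, without versions. The deposited values are MAS5 signal intensities on a linear scale. Their 2% trimmed mean was 500.1 to 500.2 on every array, so each array had been scaled to a common mean by the authors. No raw probe values were used, and no further normalization was applied for the values reported.

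Samples were grouped by line and treatment as their titles state, into 8 groups of 3 labelled biological replicates. Of the probe sets, 113 controls were left out of the tests and used only for the 3' to 5' ratios. The remaining 17621 were kept if they lay above the 40th percentile of the array, 72.6 to 106.8 units, on at least 3 arrays, which left 12111 and removed 5510. Signals were analysed as log2 of the value plus 4.56, the 10th percentile of all values. One limma model with a mean per group was fitted to all arrays (16 residual and 5.01 prior degrees of freedom, eBayes with trend). Moderated statistics were computed for 14 contrasts: each treatment with control, severe with moderate drought and re-watered with severe drought in each line, the lines in control, and the difference between the lines in each treatment. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05.

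The array annotation, of 2007, names 1 gene for 1452 probe sets and several for 1, and 16168 have no gene name. The 1108 genes so named were matched to the current RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only, in which 1060 were found. Of the genes, 887 were tested, through 1055 probe sets.

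The genes named in the text were chosen by a rule written before the data were examined. For treatments the rule takes the 8 largest rises and 8 largest falls among called probe sets of 1 gene with an informative name. All 3 arrays of one group must lie beyond the 3 of the other, and the higher group mean must be at or above the median of all tested probe sets. For line comparisons it takes the 6 largest each way. It adds up to 4 members of each gene list with the smallest adjusted p. The text names some of these.

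Of 25 gene lists defined by patterns in gene names before the data were examined, 17 had a member on the array, and 16 more were put together by symbol. Each gene was represented by its probe set with the highest mean. The 26 lists with at least 4 tested genes were tested by camera with a preset correlation of 0.01, adjusted over lists within a contrast, which gave 93 calls in 364 tests. With an estimated correlation 6 of these 93 were also called. No called list had a median and a mean of different sign (0 of 93).

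Replicate numbers were checked for pairing. Arrays of the same number in the compared groups had correlated deviations from their group means (r = 0.154 to 0.692 across genes), so the replicate number was used as a block in an alternative. The calling was also tested on simulated data made like the comparison of severe drought with control in Han21 (12111 probe sets): it recovered 22.4% of changes of 0.5, 73.1% of changes of 1 and 98.5% of changes of 2 on the log2 scale, and 9.8% of calls were false (14). Only 200 probe sets were changed there, while the comparison itself called 6968, so these rates do not carry over to it. Other alternatives were quantile normalization, median centring, a filter at the 60th percentile, no filter, 4 times the constant, no constant, eBayes without trend, a fit of only the groups compared, a limit of 2-fold, all matching probe sets, fry, and leaving out each replicate. The tools were R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.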

Results

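Transcript levels were measured in the shoots of maize seedlings at the 3-leaf stage on 24 oligonucleotide arrays hybridised with labelled RNA. The plants belonged to 2 inbred lines, Han21 and Ye478. Each line was sampled as a watered control, under moderate drought, under severe drought and after re-watering, with 3 arrays titled as biological replicates in each of the 8 groups. The description of the series speaks of 2 independent experiments, so it is uncertain what the replicates cover. The labels give neither soil water contents nor the length of the treatments. Median signals per array lay between 154.4 and 192.9 units. Replicates correlated at r = 0.939 to 0.979 on the log2 scale, computed only over probe sets with a mean signal above the median. Genes are not independent replicates. Of the probe sets for genes, 12111 were bright enough to be tested. Only 1055 of these carry a gene name, so the genes named below stand for a small part of what changed, and the number of arrays limits the precision of each value. Changes of genes and medians of gene lists are log2 fold changes, or differences of these between the lines. Errors after them are standard errors from the model of all arrays, with n = 3 arrays per group. Where a group lies under the filter level of 72.6 to 106.8 units, the size of a change depends on the constant added before taking logarithms. The lists of aquaporins, benzoxazinoid genes, cytosolic ribosomal proteins, dehydrins and LEA proteins, dividing-tissue markers, glutathione S-transferases, heat shock proteins and chaperones, and proteolysis and senescence genes were fixed before the data were examined. The other lists named here were put together by symbol from the array annotation, before any expression value was examined. That of expansins and cellulose synthases also holds bk2, lop1 and xet1. Counts of higher and lower probe sets are given without weight on which is larger, since the larger of them changed under quantile normalization or median centring in 9 of 14 comparisons. For the 17 fixed lists, counts were also adjusted over the list alone. In 45 of 238 pairs of a list and a comparison these counts differed, by at most 2 genes, and such a count is printed beside the other.

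The first principal component of the log2 signals held 42.7% of the variance and the second 32.4%. On the first, the Han21 controls scored -73.2 to -69.7, its moderate-drought arrays -5.4 to 2.3 and its severe-drought arrays 21.8 to 38.5, and the corresponding Ye478 scores were -25.6 to -22.1, 60.9 to 72.1 and 90.5 to 98.1. The re-watered arrays returned to -89.3 to -75.5 in Han21 and -14.9 to -11.6 in Ye478. The third component, with 7.5% of the variance, set them apart from the controls, at -41 to -33 against 24.9 to 25.8 in Han21 and -32.1 to -28.8 against 34.6 to 37.5 in Ye478. Of the control probe sets that report RNA integrity, an actin pair gave a log2 ratio of 3' to 5' signal of 1.87 ± 0.17 (SD, n = 3) in Han21 controls and 1.03 ± 0.32 in severe drought, and of 2.03 ± 0.24 and 1.13 ± 0.36 in Ye478. A ubiquitin pair went from 0.37 ± 0.25 to -0.07 ± 0.33 in Han21 and from 0.91 ± 0.52 to 0.26 ± 0.28 in Ye478. The pairs did not move together, with lower means in severe drought than in control for 2 of 7 in Han21 and 3 of 7 in Ye478. Another actin pair went from -3.17 ± 1 to -1.24 ± 1.08 in Han21 and from -3.11 ± 3.28 to 0.17 ± 0.97 in Ye478, and a cyclophilin pair from 0.52 ± 0.02 to 0.86 ± 0.2 and from 0.55 ± 0.12 to 0.6 ± 0.18. After re-watering the cyclophilin pair stood at 0.92 ± 0.04 in Han21 and 0.67 ± 0.12 in Ye478, and an elongation factor pair at 0.34 ± 0.25 and 0.67 ± 0.07, against 0.66 ± 0.26 and 0.91 ± 0.44 in control, so RNA integrity was not separated from treatment. Replicate 1 stood apart from replicates 2 and 3 of its own group in all 8 groups, with scores of -26.9 to -22.6 on the first component of the deviations from group means against 5.7 to 20.3 for the other replicates.

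**Figure D1:**
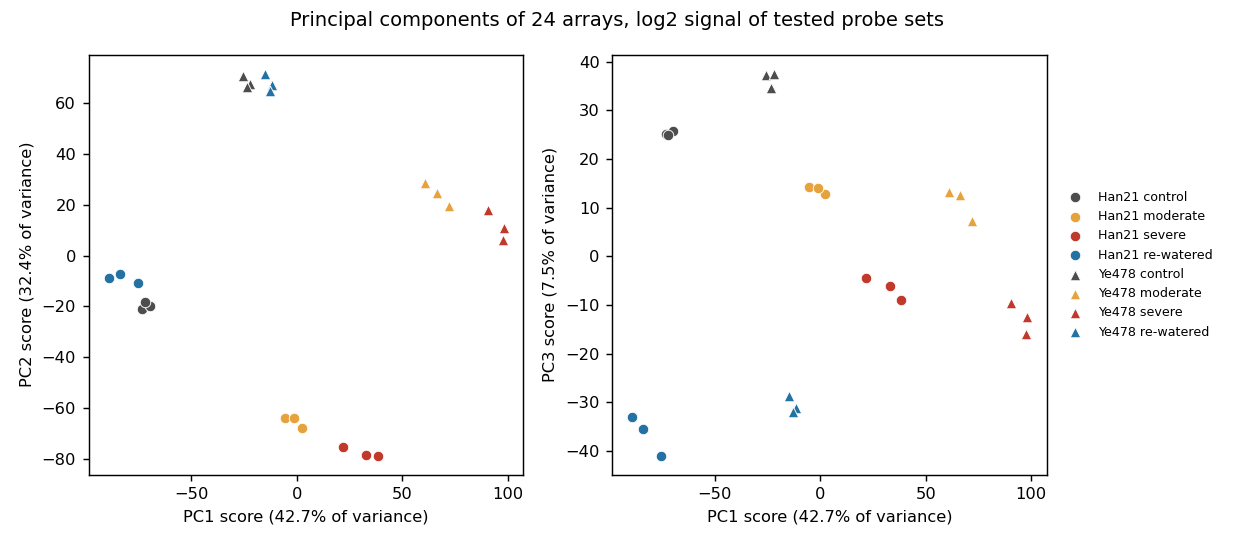
Principal component scores of the 24 arrays, computed from log2 signals of the tested probe sets (no unit); each point is 1 array, colours give the condition and circles or triangles the line. Drought moved both lines to the right on the first component (42.7% of the variance), and the re-watered arrays lay lowest on the third (7.5%).

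Moderate drought in Han21 raised transcripts of proteins that accompany cell dehydration. The LEA protein gene mlg3 rose by a log2 fold change of 5.56 ± 0.57 (n = 3, adjusted p = 1.1e-07), the dehydrin genes dhn2 and dhn1 by 3.85 ± 0.18 and 4.40 ± 0.60, and vp14, which encodes the dioxygenase of abscisic acid synthesis, by 2.22 ± 0.29. dhn1 gave the brightest signal on 2 of 3 of these arrays, so saturation is not excluded and its rise is not exact. sus2, a sucrose synthase gene, went from a signal of 81.3 ± 1.85 (SD, n = 3) to 2958 ± 150, a rise of 5.11 ± 0.17, and asn1, an asparagine synthetase gene, rose by 4.93 ± 0.19. Of the heat shock protein and chaperone genes, 8 of 9 rose (median of 1.1, camera adjusted p = 0.000258, adjusted p = 0.111 with an estimated correlation). Among them were hsp18 (3.74 ± 0.30), hsp101 (3.14 ± 0.21) and hsp18f (2.63 ± 0.25). The other gene of this list fell only when adjusted over the list alone (1 gene). The dehydrin and LEA list, with 3 of 4 genes up, was also called (median of 2.55, camera adjusted p = 0.00837, adjusted p = 0.186 with an estimated correlation).

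Among the largest falls in Han21 under moderate drought were those of the fatty acid elongase gene fae1 (-4.13 ± 0.28), the β-glucosidase gene glu1 (-3.51 ± 0.32), the glutathione S-transferase gene gst9 (-3.23 ± 0.27) and gpc3, a gene for cytosolic glyceraldehyde-3-phosphate dehydrogenase (-3.04 ± 0.31). Of 8 measured genes on the list of dividing-tissue markers, which was matched by name without hand editing, 7 fell (median of -1.53, camera adjusted p = 0.000808, adjusted p = 0.212 with an estimated correlation). They included pcna2 (-2.73 ± 0.20) and MCM7 (-2.97 ± 0.34), whose products act in DNA replication. The list of cell cycle and replication genes, put together by symbol, was not called (median of -0.40, camera adjusted p = 0.0642). In 14 comparisons camera called it in 0, with 5 at an unadjusted p under 0.05, while fry called it in 9. Over all probe sets of its genes camera called it in 7. Expansin and cellulose synthase genes, which serve the cell wall, fell in 12 of 23 cases and rose in 2 (median of -0.60, camera adjusted p = 0.00451, adjusted p = 0.336 with an estimated correlation). expB6 changed by -2.11 ± 0.24 and expB8 by -1.97 ± 0.17. Tubulin and actin-binding genes fell in 6 of 15 cases (median of -0.25, camera adjusted p = 0.0155, adjusted p = 0.402 with an estimated correlation). 11 (12 adjusted over the list alone) of 22 aquaporin genes fell (median of -0.57, camera adjusted p = 0.0392, adjusted p = 0.327 with an estimated correlation). They included Lsi6 (-2.72 ± 0.27) and tip2a (-2.57 ± 0.32). In all, 5002 probe sets differed from control, 2335 higher and 2667 lower, and 1802 of them by at least 2-fold.

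Genes known from maturing seeds were high in Han21 under severe drought, some of them already under moderate drought. glb1, which encodes a globulin storage protein of the embryo, went from a signal of 8.11 ± 6.89 (SD, n = 3) in control to 1133 ± 236, a rise of 6.60 ± 0.47 (n = 3, adjusted p = 1.81e-10), after 4.82 ± 0.47 in moderate drought. Its control signal lies under the filter level, and the rise was 7.46 with no constant and 5.46 with 4 times the constant. mlg3 rose by 7.73 ± 0.57, also from a control under the filter level, so the sizes of its rises in Han21 depend on the constant. esp5, an older name of which is EMB5, rose by 2.73 ± 0.48 and the tonoplast aquaporin gene tip3a by 4.05 ± 0.54. The rise of per-1, for a 1-Cys peroxiredoxin, was 3.18 ± 0.32. These are single genes: the list of kernel proteins was not called, with 2 of 5 up, 1 down and a median of 0.41, camera adjusted p = 0.452. Of 18 endosperm genes with a probe set, 3 were bright enough to be tested. The dehydrin and LEA list again had 3 of 4 genes up (median of 3.46, camera adjusted p = 0.018, adjusted p = 0.156 with an estimated correlation, adjusted p = 0.0544 without replicate 1). Of the heat shock and chaperone genes, 7 of 9 rose (median of 1.23, camera adjusted p = 0.00477, adjusted p = 0.156 with an estimated correlation). sus2 rose by 5.90 ± 0.17, asn1 by 5.90 ± 0.19, and lkrsdh1, for the enzyme that opens lysine breakdown, by 3.12 ± 0.15.

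In Han21 under severe drought 21 of 23 expansin and cellulose synthase genes fell and 2 rose (median of -2.23, camera adjusted p = 1.14e-08, adjusted p = 0.136 with an estimated correlation). The changes were -5.04 ± 0.49 for expa1, -4.02 ± 0.24 for expB6 and -2.41 ± 0.13 for CesA-1. 12 of 15 tubulin and actin-binding genes fell (median of -1.10, camera adjusted p = 4.12e-05, adjusted p = 0.156 with an estimated correlation), with tua5 at -2.42 ± 0.13 and TUBB2 at -2.66 ± 0.21. Dividing-tissue markers fell in 7 of 8 cases (median of -2.18, camera adjusted p = 0.00131, adjusted p = 0.156 with an estimated correlation). In replicate 1 of each group, expa1 lay on average 0.65 log2 units above replicates 2 and 3. Of 13 genes of the photosynthetic light reactions, 10 fell (median of -0.74, camera adjusted p = 0.0033, adjusted p = 0.414 with an estimated correlation). The light-harvesting gene lhcb6 (-2.41 ± 0.23) and the Rubisco activase gene rca1 (-1.23 ± 0.15) fell. NNR1, a nitrate reductase gene, changed by -3.03 ± 0.26 and sps1, for sucrose phosphate synthase, by -2.91 ± 0.21. 6968 probe sets differed from control, 3490 higher and 3478 lower, and 2950 by at least 2-fold.

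Between moderate and severe drought in Han21, the cellulose synthase gene cesa10 went from a signal of 936 ± 91.5 (SD, n = 3) to 139.7 ± 55.7, a change of -2.77 ± 0.21 (n = 3, adjusted p = 1.13e-08), and CesA12 and bk2, a COBRA-like gene of secondary walls, changed by -2.40 ± 0.20 and -3.16 ± 0.19. Over the expansin and cellulose synthase list, 16 of 23 genes fell and 1 rose (median of -1.36, camera adjusted p = 4.89e-16, adjusted p = 0.0115 with an estimated correlation). Phenylpropanoid and lignin genes fell in 5 of 9 cases (median of -0.62, camera adjusted p = 0.00168, adjusted p = 0.03 with an estimated correlation). Among them were 4CL (-1.66 ± 0.21) and ccr2 (-1.52 ± 0.28). Of the tubulin and actin-binding genes 9 of 15 fell (median of -0.93, camera adjusted p = 3.09e-08, adjusted p = 0.0494 with an estimated correlation). 8 of 13 light-reaction genes fell (median of -0.58, camera adjusted p = 8.88e-05, adjusted p = 0.351 with an estimated correlation). The benzoxazinoid list was also called, downward, with a camera adjusted p of at most 0.0399 when a replicate number was left out. The antioxidant enzyme list was called upward, but with a camera adjusted p of 0.0818 without replicate 2. Neither was called here with an estimated correlation. glb1 and tip3a rose by 1.78 ± 0.47 and 3.73 ± 0.54. The adjusted p of glb1 was 0.0112, but 0.126 with no constant, 0.0528 without Han21 severe replicate 3 and 0.0646 without replicate 1 of every group. Of the genes that name patterns put on the list of dividing-tissue markers, only krp6 (-2.55 ± 0.22) passed the test. Its fall alone is not read as less cell division. 2181 probe sets differed, 915 of them higher in severe drought. These counts were 1397 and 457 without replicate 1, 1519 and 514 without Han21 moderate replicate 3, 1523 and 564 without Han21 severe replicate 3, 3263 and 1563 with the replicate number as a block, and 2088 and 701 with median centring.

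Under moderate drought in Ye478, mlg3 rose by 6.14 ± 0.57 (n = 3, adjusted p = 1.55e-08), dhn2 by 3.51 ± 0.18, vp14 by 2.97 ± 0.29 and sus2 by 4.22 ± 0.17. The glutathione S-transferase gene gst19 rose from a signal of 14.7 ± 11.6 (SD, n = 3) to 548 ± 61.8, a change of 5.00 ± 0.24 that was 5.5 with no constant and 4.15 with 4 times the constant, as its control lies under the filter level. tip3a rose by 5.32 ± 0.54 and glb1 by 3.99 ± 0.47. The dehydrin and LEA list had 3 of 4 genes up (median of 2.62, camera adjusted p = 0.019, adjusted p = 0.141 with an estimated correlation). The heat shock and chaperone list had 8 of 9 up (median of 0.98, camera adjusted p = 0.00113, adjusted p = 0.139 with an estimated correlation). Antioxidant enzyme genes rose in 10 of 15 cases (median of 0.60, camera adjusted p = 0.00301, adjusted p = 0.0596 with an estimated correlation), including the catalase gene cat1 (1.35 ± 0.11) and the ferritin gene fer2 (1.14 ± 0.14). expa1 changed by -5.22 ± 0.49, fae1 by -4.92 ± 0.28 and gpc3 by -4.51 ± 0.31. Of the expansin and cellulose synthase genes 18 of 23 fell (median of -1.50, camera adjusted p = 5.25e-08, adjusted p = 0.08 with an estimated correlation), and of the tubulin and actin-binding genes 11 of 15 (median of -0.72, camera adjusted p = 0.000176, adjusted p = 0.141 with an estimated correlation). Among 8 dividing-tissue markers 7 fell (median of -2.57, camera adjusted p = 0.000253, adjusted p = 0.139 with an estimated correlation), and MCM7 changed by -3.48 ± 0.34. 5886 probe sets differed from control, 2858 higher and 3028 lower, and 2323 by at least 2-fold.

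In Ye478 under severe drought tip3a rose by 7.39 ± 0.54 (n = 3, adjusted p = 1.67e-10), its relative tip3b by 5.20 ± 0.34, glb1 by 6.06 ± 0.47, per-1 by 5.67 ± 0.32 and esp5 by 4.33 ± 0.48. The oleosin gene ole1 rose by 3.51 ± 0.39. The list of kernel proteins was not called here either, with 2 of 5 genes up, 3 down and a median of -0.41, camera adjusted p = 0.785. Another rise was that of the cell-wall invertase gene incw1, by 3.72 ± 0.21. Rises covered 3 of 4 dehydrin and LEA genes (median of 4.22, camera adjusted p = 0.0126, adjusted p = 0.119 with an estimated correlation). They covered 8 of 9 heat shock and chaperone genes (median of 1.74, camera adjusted p = 0.00314, adjusted p = 0.119 with an estimated correlation). Antioxidant enzyme genes rose in 11 of 15 cases (median of 0.80, camera adjusted p = 0.00636, adjusted p = 0.0701 with an estimated correlation). cesa10 fell from a signal of 591 ± 30.3 (SD, n = 3) to 20.8 ± 2.97, a change of -4.56 ± 0.21, and the β-tubulin gene tub5 from 3543 ± 331 to 129 ± 57.6, a change of -4.82 ± 0.25.

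All 4 measured genes of the list for benzoxazinoids, defence compounds of grasses, fell in Ye478 under severe drought (median of -2.55, camera adjusted p = 0.00865, adjusted p = 0.0701 with an estimated correlation). They were the synthesis genes bx6 (-3.79 ± 0.21) and bx1 (-2.03 ± 0.24) and the β-glucosidase genes glu1 (-3.08 ± 0.32) and glu2 (-1.13 ± 0.19). Expansin and cellulose synthase genes fell in 20 of 23 cases (median of -2.84, camera adjusted p = 4.29e-07, adjusted p = 0.0701 with an estimated correlation). Tubulin and actin-binding genes fell in 11 of 15 (median of -1.67, camera adjusted p = 0.000254, adjusted p = 0.119 with an estimated correlation), and dividing-tissue markers in 7 of 8 (median of -2.44, camera adjusted p = 0.00336, adjusted p = 0.194 with an estimated correlation). Of the light-reaction genes 11 of 13 fell (median of -0.87, camera adjusted p = 0.00336, adjusted p = 0.431 with an estimated correlation). Cytosolic ribosomal protein genes fell in 7 of 12 cases (median of -0.61, camera adjusted p = 0.0484, adjusted p = 0.119 with an estimated correlation, adjusted p = 0.131 without replicate 1). CAT3, another catalase gene, changed by -1.32 ± 0.17 while cat1 rose by 1.87 ± 0.11. 7704 probe sets differed from control, 3665 higher and 4039 lower, and 3627 by at least 2-fold.

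From moderate to severe drought in Ye478, tip3b rose by 4.49 ± 0.34 (n = 3, adjusted p = 2.95e-08), per-1 by 2.98 ± 0.32 and incw1 by 2.53 ± 0.21, whereas ivr2, a vacuolar invertase gene, changed by -2.47 ± 0.16. 4 of 4 genes of the benzoxazinoid list, which was also called downward at this step in Han21, fell (median of -1.15, camera adjusted p = 0.000752, adjusted p = 0.0301 with an estimated correlation). So did 9 of 13 light-reaction genes (median of -0.64, camera adjusted p = 2.15e-05, adjusted p = 0.303 with an estimated correlation). Of the expansin and cellulose synthase genes 14 of 23 fell (median of -0.95, camera adjusted p = 2.15e-05, adjusted p = 0.283 with an estimated correlation). 5 of 9 heat shock and chaperone genes rose (median of 0.73, camera adjusted p = 0.0327, adjusted p = 0.303 with an estimated correlation, adjusted p = 0.0693 with the replicate number as a block, adjusted p = 0.122 without replicate 3). 2891 probe sets differed, 1219 higher and 1672 lower in severe drought (763 and 1212 without replicate 1), and 696 by at least 2-fold.

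**Figure D2:**
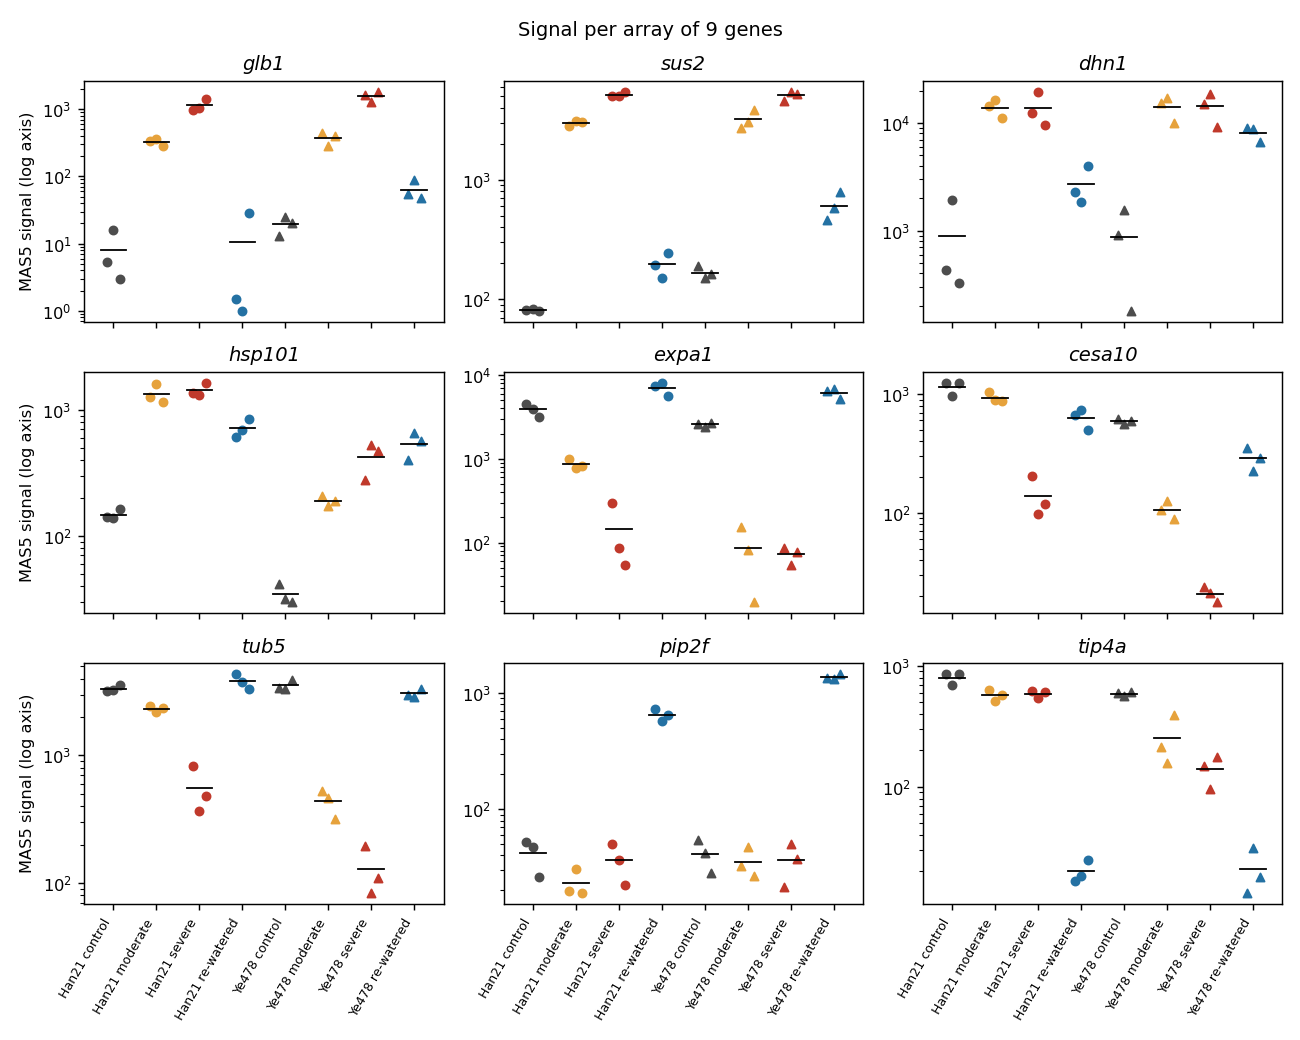
MAS5 signal on a log axis for 9 genes in each of the 8 groups; points are arrays, circles for Han21 and triangles for Ye478, and bars are group means. glb1, sus2 and dhn1 rose under drought in both lines, expa1, cesa10 and tub5 fell from moderate to severe drought in Han21 and from control to severe drought in Ye478, and from severe drought to re-watering pip2f rose and tip4a fell in both lines, with tip4a at 20.1 ± 4.30 (mean ± SD, n = 3) in Han21 against 798 ± 92.1 in its control.

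Fold changes of the 2 lines, which share no arrays, were correlated across the 12111 probe sets. Pearson's r was 0.811 in moderate drought, 0.851 in severe drought and 0.556 after re-watering, and Spearman's rho was 0.766, 0.812 and 0.435. Genes are not independent replicates, so no p is attached. In severe drought 2633 probe sets were called higher and 2840 lower in both lines, against 1056 and 1160 for independent lists of the same sizes, and 165 were called in opposite directions. In moderate drought the counts were 1771, 1974 and 74 (551 and 667 for independent lists), and after re-watering 659, 1025 and 159 (229 and 379).

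From severe drought to re-watering, expa1 rose by 5.90 ± 0.49 in Han21 (n = 3, adjusted p = 1.23e-09) and by 6.33 ± 0.49 in Ye478. glk1, a GOLDEN2-LIKE transcription factor gene of chloroplast development, rose by 5.13 ± 0.20 and 4.69 ± 0.20, NNR1 by 4.52 ± 0.26 and 4.17 ± 0.26, and the plasma membrane aquaporin gene pip2f by 4.05 ± 0.31 and 5.13 ± 0.31. Severe-drought signals of pip2f, 22.3 to 50.4 and 21.6 to 50.6, lie under the filter level, so the sizes of its rises depend on the constant. Of the expansin and cellulose synthase genes, 20 of 23 rose in Han21 (median of 1.96, camera adjusted p = 2.07e-07, adjusted p = 0.11 with an estimated correlation). In Ye478 19 rose (median of 2.36, camera adjusted p = 5.36e-08, adjusted p = 0.0889 with an estimated correlation). 12 of 15 tubulin and actin-binding genes rose in each line. The list gave a median of 0.95, camera adjusted p = 0.000943, adjusted p = 0.186 with an estimated correlation in Han21 and a median of 1.38, camera adjusted p = 0.000383, adjusted p = 0.156 with an estimated correlation in Ye478. 7 of 8 dividing-tissue markers rose in Han21 (median of 2.12, camera adjusted p = 0.00114, adjusted p = 0.186 with an estimated correlation). In Ye478 6 rose (median of 1.26, camera adjusted p = 0.0407, adjusted p = 0.361 with an estimated correlation, adjusted p = 0.0652 with the replicate number as a block, adjusted p = 0.0908 without replicate 3). MCM6 rose by 3.62 ± 0.30 and 3.44 ± 0.30.

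The light-reaction genes rose after re-watering in 10 of 13 cases in each line. Their list gave a median of 0.80, camera adjusted p = 0.00396, adjusted p = 0.445 with an estimated correlation in Han21 and a median of 0.82, camera adjusted p = 0.000781, adjusted p = 0.355 with an estimated correlation in Ye478. The list of Calvin cycle and C4 photosynthesis genes was called in Ye478, with 7 of 10 up (median of 0.76, camera adjusted p = 0.0204, adjusted p = 0.361 with an estimated correlation). In Han21 it was not called, with 6 of 10 up (median of 0.45, camera adjusted p = 0.147), and the difference between the lines was not tested for this step. Aquaporin genes rose in 14 of 22 cases in Han21 (median of 1.32, camera adjusted p = 0.00396, adjusted p = 0.11 with an estimated correlation). In Ye478 13 of them rose (median of 0.79, camera adjusted p = 0.0226, adjusted p = 0.156 with an estimated correlation). Cytosolic ribosomal protein genes rose in 9 of 12 cases in each line, with a median of 0.49, camera adjusted p = 0.0214, adjusted p = 0.11 with an estimated correlation in Han21. In Ye478 the list had a median of 0.56, camera adjusted p = 0.00642, adjusted p = 0.083 with an estimated correlation. In Ye478, 19 of 28 glutathione S-transferase genes rose (median of 1.36, camera adjusted p = 0.0101, adjusted p = 0.156 with an estimated correlation). Falling genes included glb1 (-6.76 ± 0.47 in Han21, -4.57 ± 0.47 in Ye478), with sus2 (-4.71 ± 0.17 and -3.08 ± 0.17), lkrsdh1 (-3.83 ± 0.15 and -3.27 ± 0.15) and per-1 (-2.81 ± 0.32 and -4.82 ± 0.32). 4 of 4 dehydrin and LEA genes fell in Han21 (median of -2.30, camera adjusted p = 0.0214, adjusted p = 0.186 with an estimated correlation). In Ye478 3 fell (median of -1.35, camera adjusted p = 0.0491, adjusted p = 0.239 with an estimated correlation, adjusted p = 0.0652 with the replicate number as a block, adjusted p = 0.0589 without replicate 3). 7849 probe sets differed between re-watered and severe-drought plants in Han21, 3870 higher and 3979 lower, and 7944 in Ye478, 3818 higher and 4126 lower.

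The samples taken after re-watering were set against severe drought and against the control group of their line. The labels do not say when the re-watered plants were sampled, so age and time of sampling were not separated from re-watering. Of the 6968 probe sets called under severe drought in Han21, 5516 (79.2%) changed the opposite way on re-watering, and 1356 (19.5%) were still called in the drought direction against control. Those called beyond control, that is, against the drought direction, numbered 1269 (18.2%). Each group was counted on its own, so the groups overlap. In Ye478 the figures were 6229 of 7704 (80.9%), 1814 (23.5%) and 708 (9.2%). Without replicate 2, the shares still called were 11.2% in Han21 and 15.4% in Ye478, and those beyond control 10.7% and 4.1% (5.8% in Ye478 without replicate 1). Independent lists would share 2258 and 2522 opposite calls, 1218 and 1098 remaining calls and 1218 and 1082 calls beyond control. These comparisons share arrays. In 20 simulations with no return at all 0% changed the opposite way, and with a complete return 0% remained called and 0% were called beyond control. In both, the counted contrast held no change for any probe set, so about 0% was set in advance. These values do not calibrate the shares above. Fold changes of severe drought and re-watering, each against control, correlated at 0.094 in Han21 and 0.417 in Ye478 across probe sets, with covariances of 0.071 and 0.385. Simulated groups without any change, compared with shared controls, gave a correlation of 0.496 and a covariance of 0.03. Simulated noise was independent between arrays, while real arrays of the same replicate number shared deviations, so these values are no exact baseline. Among probe sets at least 2-fold changed in severe drought, 8.4% in Han21 and 17.8% in Ye478 were still called and at least 2-fold from control in the same direction, and 6.4% and 2.1% in the other.

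**Figure D3:**
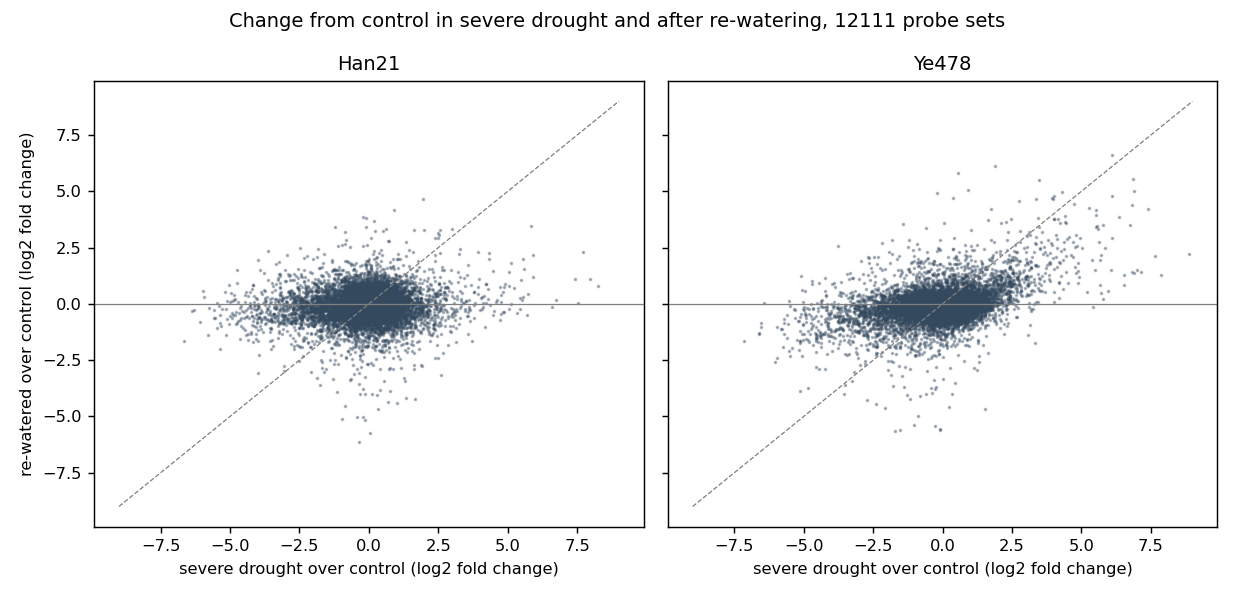
Log2 fold change of re-watered over control plants (vertical axis) against that of severe drought over control (horizontal axis) for 12111 probe sets in Han21 (left) and Ye478 (right); each point is a probe set, and the dashed line marks equal change. The correlation was 0.094 in Han21 and 0.417 in Ye478.

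In re-watered Han21 the plasma membrane aquaporin genes pip2f and pip1e were above control by 3.86 ± 0.31 (n = 3, adjusted p = 4.2e-09) and 3.33 ± 0.23, and the tonoplast aquaporin gene tip4a was below it, at -5.03 ± 0.27. In Ye478 the 3 genes differed by 4.94 ± 0.31, 5.08 ± 0.23 and -4.61 ± 0.27, and there tip4a was already below control in moderate drought (-1.30 ± 0.27). Control signals of pip2f, 26.2 to 52.6 in Han21 and 28.5 to 54.2 in Ye478, lie under the filter level, as do re-watered signals of tip4a. The sizes of these changes therefore depend on the constant. The aquaporin list was called upward in both. In Han21 10 (11 adjusted over the list alone) of 22 of its genes were up, with a median of 0.50, camera adjusted p = 0.00295, adjusted p = 0.0755 with an estimated correlation, and in Ye478 11 (12 adjusted over the list alone), with a median of 0.54, camera adjusted p = 0.000358, adjusted p = 0.0615 with an estimated correlation. The thiamine synthesis genes thi1 and thi2 lay at -4.53 ± 0.19 and -3.23 ± 0.27 in Han21 and at -4.20 ± 0.19 and -4.97 ± 0.27 in Ye478. GBSSIIa, for a granule-bound starch synthase, and gln2, for a glutamine synthetase, were higher by 3.23 ± 0.23 and 2.92 ± 0.28 in Han21 and by 2.82 ± 0.23 and 1.65 ± 0.28 in Ye478. The hydroperoxide lyase gene hpl1 was lower, at -2.44 ± 0.25 and -2.25 ± 0.25.

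The list of proteolysis and senescence genes holds proteases and protease inhibitors, and 5 of 6 lay below control after re-watering in Han21 (median of -1.07, camera adjusted p = 0.00407, adjusted p = 0.0755 with an estimated correlation). In Ye478 3 did (median of -0.93, camera adjusted p = 0.0123, adjusted p = 0.0808 with an estimated correlation, adjusted p = 0.0515 without replicate 1). Among them were the cysteine protease genes see2b (-1.44 ± 0.13 and -1.93 ± 0.13) and ccp2 (-1.18 ± 0.19 and -1.58 ± 0.19). Heat shock and chaperone genes were above control in 6 of 9 cases in each line. Their list gave a median of 0.76, camera adjusted p = 0.000687, adjusted p = 0.0755 with an estimated correlation in Han21 and a median of 2.12, camera adjusted p = 1.76e-07, adjusted p = 0.0311 with an estimated correlation in Ye478. In Ye478 hsp18f was higher by 4.77 ± 0.25, mlg3 by 5.03 ± 0.57 and wip1, a wound-induced inhibitor gene, by 4.98 ± 0.32. Of 8 dividing-tissue markers 5 (6 adjusted over the list alone) were lower (median of -0.73, camera adjusted p = 0.0123, adjusted p = 0.256 with an estimated correlation, adjusted p = 0.0578 without replicate 3). 4234 probe sets differed from control in Han21 (1906 higher, 2328 lower) and 3428 in Ye478 (1458 higher, 1970 lower). With quantile normalization Han21 had 2300 higher and 2224 lower, and with median centring Ye478 had 1751 higher and 1592 lower.

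**Figure D4:**
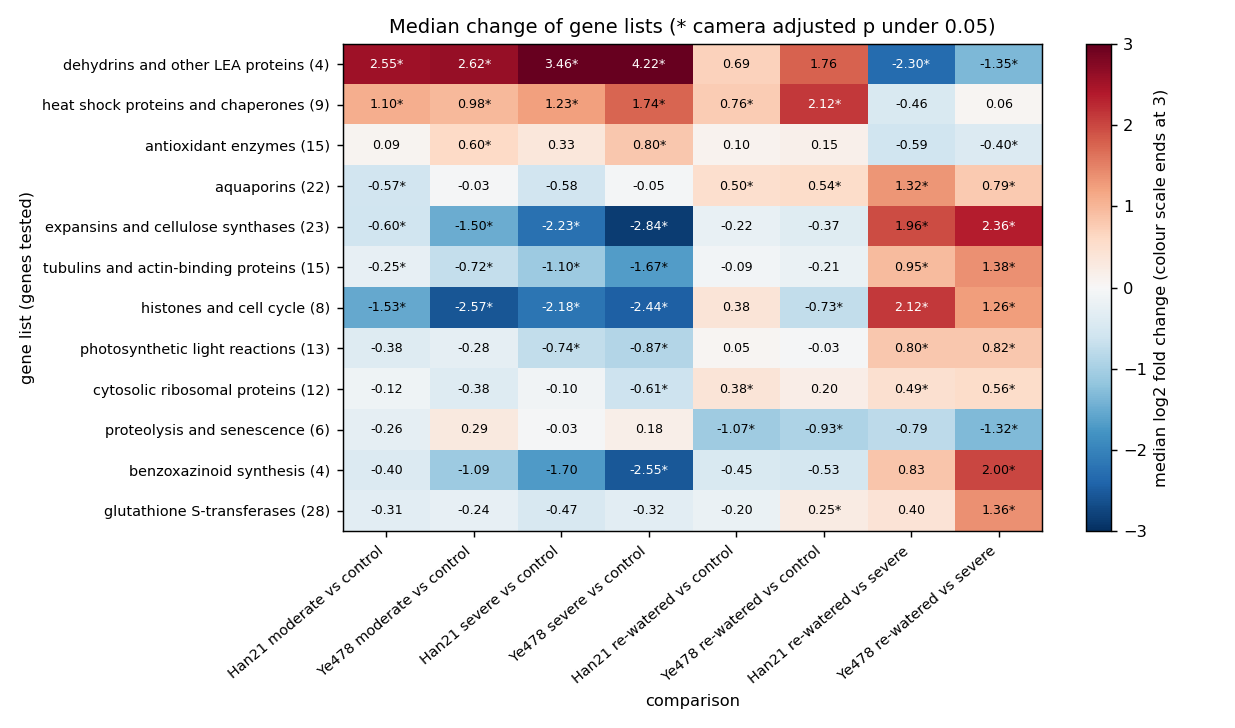
Median log2 fold change of 12 gene lists (number of tested genes in parentheses) in 8 comparisons; red is higher, blue lower, the colour scale ends at 3, and an asterisk marks a camera adjusted p under 0.05. Expansins and cellulose synthases went from a median of -2.84 in Ye478 under severe drought to -0.37 after re-watering, both against control. Aquaporins were called above control in both lines after re-watering, though not with an estimated correlation. Of the 93 camera calls in all comparisons, 6 were also made with an estimated correlation.

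The lines differed before any treatment. In controls, gst19 was higher in Han21 by 6.42 ± 0.24 (n = 3, adjusted p = 3.49e-14), with a signal of 1471 ± 133 (SD, n = 3) against 14.7 ± 11.6 in Ye478, and the lipoxygenase gene lox3 by 4.22 ± 0.31. The Ye478 signal of gst19 lies under the filter level, and its difference was 6.93 with no constant and 5.55 with 4 times the constant. hsp101 and pip1e were higher in Han21 by 1.98 ± 0.21 and 3.22 ± 0.23. The spermidine synthase gene spds2, at -6.39 ± 0.33, and the catalase gene CAT3, at -2.03 ± 0.17, were lower in Han21, as was the pathogenesis-related gene pr5 (-3.04 ± 0.45). 3944 probe sets differed, 2087 higher in Han21 and 1857 lower, 1704 of them by at least 2-fold. By limma's camera 0 of 26 gene lists were called and 0 had an unadjusted p under 0.05, while fry called 10. Probe sets of the same gene gave this difference unevenly, with a correlation of 0.26 across 121 genes against 0.899 for the response to severe drought.

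Whether the lines responded differently to drought was tested as the Han21 change minus the Ye478 change, so that a positive value is called a higher Han21 response. These words follow the sign, not the size: for a gene that fell in both lines, a higher response is a smaller fall in Han21. In moderate drought, 986 probe sets differed, 533 with the higher value in Han21. Of the expansin and cellulose synthase genes, 13 of 23 had a higher Han21 response (median of 1.07, camera adjusted p = 2.06e-09, adjusted p = 0.0511 with an estimated correlation). The difference was 2.16 ± 0.30 for cesa10 (n = 3, adjusted p = 8.6e-05), 2.32 ± 0.27 for bk2 and 3.07 ± 0.70 for expa1. Signals of expa1 in Ye478 under moderate drought were 19.4 to 154.2, partly under the filter level, so the size of its difference depends on the constant. Tubulin and actin-binding genes also had a higher Han21 response (median of 0.24, camera adjusted p = 0.00118, adjusted p = 0.229 with an estimated correlation), with tub5 at 2.50 ± 0.36. tip3a and gst19 responded more in Ye478, with differences of -5 ± 0.77 and -4.51 ± 0.33, the second of which was -5.01 with no constant and -3.67 with 4 times the constant. The aquaporin list was called downward in moderate drought in Han21 and was not called in Ye478. It had a lower Han21 response (median of -0.58, camera adjusted p = 0.0136, adjusted p = 0.153 with an estimated correlation). So did the antioxidant enzyme list (median of -0.36, camera adjusted p = 0.00245, adjusted p = 0.0347 with an estimated correlation), with the catalase gene cat2 at -2.22 ± 0.29. The count was 1607 with the replicate number as a block (859 of them with the higher value in Han21) and 564 without replicate 1 (315).

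In severe drought 1959 probe sets differed between the responses (3041 with the block), 1055 with the higher value in Han21 (1683 with the block), and camera called 0 of 26 lists, with 6 at an unadjusted p under 0.05 and 5 called by fry. tip3b had a lower Han21 response, with a difference of -5.01 ± 0.48 (n = 3, adjusted p = 4.8e-07), as did gst19 (-4.45 ± 0.33), ole1 (-3.10 ± 0.55), incw1 (-2.61 ± 0.30) and ciszog1, which encodes a cis-zeatin glucosyltransferase (-3.51 ± 0.30). asn1 differed by 2.34 ± 0.26 and CAT3 by 1.55 ± 0.24, higher in the Han21 response.

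After re-watering 1665 probe sets differed between the lines in their distance from control, 749 with the higher value in Han21. The replication gene pcna1 had a higher Han21 response, by 1.16 ± 0.18 (n = 3, adjusted p = 0.000173), as had MCM6, by 2 ± 0.43 (adjusted p = 0.0035, but 0.0707 without replicate 1), and 4 (6 adjusted over the list alone) of 8 dividing-tissue markers did so (median of 1.13, camera adjusted p = 0.000335, adjusted p = 0.197 with an estimated correlation). Heat shock and chaperone genes were lower in the Han21 response in 5 (6 adjusted over the list alone) of 9 cases (median of -0.87, camera adjusted p = 0.014, adjusted p = 0.269 with an estimated correlation, adjusted p = 0.0543 with the replicate number as a block). hsp18f stood at -3.57 ± 0.36 and hsp101 at -1.57 ± 0.30. For hsp101, re-watered signals were 613.9 to 840.5 in Han21 and 402.3 to 653.4 in Ye478. Its controls were 138.1 to 162.9 and 29.7 to 41.7, the latter under the filter level. The negative difference for hsp101 therefore does not mean a lower signal in re-watered Han21, and its size depends on the constant. Of 28 glutathione S-transferase genes 8 (9 adjusted over the list alone) were lower (median of -0.32, camera adjusted p = 0.00164, adjusted p = 0.197 with an estimated correlation). dhn2 differed by -1.97 ± 0.25, vp14 by -2.11 ± 0.41 and PPCK1, for a kinase of phosphoenolpyruvate carboxylase, by -3.12 ± 0.23. The count was 2906 with the replicate number as a block, with 1476 of them higher in Han21, and 783 without replicate 1, with 262 higher. The number higher in Han21 was 415 without Han21 control replicate 2, 458 without Han21 re-watered replicate 1, 421 without Ye478 control replicate 3 and 473 without Ye478 re-watered replicate 1.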

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

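Both ways of reordering the deviations from additive effects, and leaving out each replicate number in turn, were the tests of this part chosen after the results were seen.

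Some responses to drought differed between Han21 and Ye478 when the difference itself was tested, at an adjusted p under 0.05. Of the 12 list differences below, with the preset correlation, that of antioxidant enzymes alone was also called with an estimated correlation. In moderate drought Han21 minus Ye478 gave, for expansins and cellulose synthases, a median of 1.07, camera adjusted p = 2.06e-09, adjusted p = 0.0511 with an estimated correlation. Phenylpropanoid and lignin genes had a median of 0.63, camera adjusted p = 0.0343, adjusted p = 0.145 with an estimated correlation, adjusted p = 0.0632 without replicate 2. Fermentation and glycolysis had a median of 0.26, camera adjusted p = 0.0345, adjusted p = 0.511 with an estimated correlation, adjusted p = 0.151 without replicate 1. Tubulins and actin-binding proteins had a median of 0.24, camera adjusted p = 0.00118, adjusted p = 0.229 with an estimated correlation. Starch and sucrose metabolism had a median of 0.21, camera adjusted p = 0.0152, adjusted p = 0.238 with an estimated correlation, adjusted p = 0.0632 without replicate 2. Antioxidant enzymes had a median of -0.36, camera adjusted p = 0.00245, adjusted p = 0.0347 with an estimated correlation. Aquaporins had a median of -0.58, camera adjusted p = 0.0136, adjusted p = 0.153 with an estimated correlation. The list of proteolysis and senescence, which includes protease inhibitors, had a median of -0.62, camera adjusted p = 0.0345, adjusted p = 0.153 with an estimated correlation, adjusted p = 0.207 without replicate 2. After re-watering, dividing-tissue markers had a median of 1.13, camera adjusted p = 0.000335, adjusted p = 0.197 with an estimated correlation. Glutathione S-transferases had a median of -0.32, camera adjusted p = 0.00164, adjusted p = 0.197 with an estimated correlation. Heat shock proteins and chaperones had a median of -0.87, camera adjusted p = 0.014, adjusted p = 0.269 with an estimated correlation, adjusted p = 0.0543 with the replicate number as a block. Dehydrins, LEA and ABA-responsive proteins put together by symbol had a median of -1.05, camera adjusted p = 0.015, adjusted p = 0.197 with an estimated correlation. By gene, the differences of log2 fold changes were as follows. Higher and lower follow the sign of the difference, not the size of the change in either line.

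In moderate drought the Han21 response was higher for expa1 (3.07), tub5 (2.50), bk2 (2.32), cesa10 (2.16), expB6 (1.64), asn1 (1.55), gpc3 (1.47) and sus2 (0.89). It was lower for tip3a (-5), gst19 (-4.51), cat2 (-2.22), Lsi6 (-1.62) and glu1 (-1.58). In severe drought the Han21 response was higher for asn1 (2.34), tub5 (2.16), bx1 (1.69), glu2 (1.61), CAT3 (1.55), cesa10 (1.51), sus2 (1.02) and tua5 (0.59). It was lower for tip3b (-5.01), gst19 (-4.45), ciszog1 (-3.51), tip3a (-3.34), ole1 (-3.10), incw1 (-2.61), per-1 (-2.50) and cat1 (-0.68). After re-watering the Han21 response was higher for MCM6 (2), thi2 (1.74), gln2 (1.27) and pcna1 (1.16). It was lower for hsp18f (-3.57), PPCK1 (-3.12), mlg3 (-2.72), wip1 (-2.53), vp14 (-2.11), dhn2 (-1.97), pip1e (-1.75) and hsp101 (-1.57). For sus2, control signals were 79.6 to 83.2 in Han21 and 149.6 to 189.7 in Ye478. Its moderate-drought signals were 2786.6 to 3065.7 and 2722.1 to 3835.9, and its severe-drought signals 4980.3 to 5409.5 and 4529.3 to 5397.7. The positive differences for sus2 therefore do not mean a higher signal in Han21 under drought.

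The counts of probe sets whose change from control differed between the lines were 986 in moderate drought, 1959 in severe drought and 1665 after re-watering. Exchanging arrays between treatment and control within the lines gave as many in 13, 16 and 7 of 100 splits, the real one included. The highest other counts, 4523, 8582 and 5047, were several times the real ones. Such splits set the drought effect of one line against that of the other, which is a structure of the samples, so this test does not exclude chance for these counts. When the effects of line and treatment were kept additive and the deviations reordered, 1, 2 and 1 of 100 orders gave as many, with highest other counts of 121, 2349 and 415. These orders treat the arrays as exchangeable, although arrays of the same replicate number share deviations. With orders changed only among arrays of the same replicate number, 1, 1 and 1 of 100 gave as many, with highest other counts of 8, 172 and 356, so a chance order within replicate numbers was excluded.

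For each comparison of 2 groups, 10 splits of the 6 arrays are too few for a share under 0.05. The counts and the highest other counts were 5002 and 0 for moderate drought in Han21, 6968 and 1 for severe drought, 2181 and 1 for severe with moderate drought, 7849 and 3 for re-watered with severe drought and 4234 and 4 for re-watered with control. In Ye478 they were 5886 and 0, 7704 and 0, 2891 and 2, 7944 and 1, and 3428 and 0. For the lines in control they were 3944 and 0. Among the 4 splits that part all replicate pairs, the highest other count was 0, or 1 for re-watered with severe drought in Ye478.

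The differences between the lines in control may in part come from sequence differences at the probes. Across 121 genes with several probe sets, pairs of probe sets of a gene correlated at 0.26 for the difference between lines and at 0.899 for the response to severe drought (Spearman's rho 0.464 and 0.825). The correlations differed by 0.638 (95% bootstrap interval 0.323 to 0.971). The values spread less for the line difference (SD 0.8 against 1.33), which can lower a correlation as well. How much it did so here was not tested. A difference in expression between the genotypes stays open as an explanation for any gene.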

How the results depend on the processing

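Leaving out replicate 1 from every group, and each replicate number in turn for the gene lists, the shared response and the return, and all alternatives for calls beyond control, were chosen only after the results were seen.

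The growth, stress and seed genes named in the text kept their direction and their call under every alternative that gave them a value in 145 of 147 results for a gene in a comparison (2468 checks). The exceptions kept their direction and lost their call. These were glb1 in severe against moderate drought in Han21, with an adjusted p of 0.126 with no constant, 0.0528 without Han21 severe replicate 3 and 0.0646 without replicate 1, and MCM6 in the line difference after re-watering, with 0.0707 without replicate 1. Among probe sets called with and without an alternative, 0 changed sign, and quantile normalization or median centring shifted the median of all genes by less than 0.1.

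Counts of probe sets stayed within 1.5 times their value under quantile normalization, median centring, both other filters, both other constants, eBayes without trend and a fit of only the groups compared. With the replicate number as a block the line differences moved to 1607 in moderate drought, 3041 in severe drought and 2906 after re-watering. The larger of the higher and lower counts changed under at least 1 alternative in 10 of 14 comparisons, and in 9 under quantile normalization or median centring. A block removes the replicate deviations from the residual spread. Without replicate 1 the comparison of severe with moderate drought in Han21 gave 1397, and the line differences gave 564 in moderate drought and 783 after re-watering, with fewer arrays. Over all alternatives that leave out arrays these 3 counts ranged from 1397 to 1845, from 564 to 910 and from 783 to 1907.

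Of the 93 calls of the gene list tests, 6 were also made with an estimated correlation. fry, which does not compare a list with other genes, made 207. The share of severe-drought calls still called after re-watering in Han21 was 8.4% with a limit of 2-fold, against 19.5%; the cause was not tested. It was 11.2% to 16.8% when a replicate number was left out, with fewer arrays, and 15.4% to 19.7% in Ye478, against 23.5%. The share called beyond control was 6.4% in Han21 and 2.1% in Ye478 with the limit of 2-fold, against 18.2% and 9.2%, and the cause was not tested. With a replicate number left out it was 10.7% to 15.2% and 4.1% to 6.6%. Dim probe sets limit what could be seen: 5510 of 17621 stayed under the signal filter.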

Other observations

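The tests of this part, other than those of array scaling and of the kernel protein list, were chosen only after the results were seen.

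Re-watered Ye478 lay further in the drought direction than re-watered Han21 among genes that both lines had changed alike. Of 5473 probe sets called in the same direction under severe drought in both lines, 883 differed between the lines after re-watering. In 713 of these (80.7%) Ye478 lay further in the drought direction, and in 170 Han21 did. The 713 do not all stand for a response kept by Ye478: in 331 Ye478 was still called in the drought direction and Han21 was not called beyond control, in 282 Han21 was called beyond control and Ye478 was not still called, in 79 both held, and in 21 neither. The median share of the severe change that remained was 1% in Han21 and 10.4% in Ye478. mlg3 stood at 5.03 ± 0.57 over control in re-watered Ye478 (n = 3), and the difference between the lines, Han21 minus Ye478, was -2.72. The share with Ye478 further in the drought direction was 79.1% after quantile normalization, 75.6% of 1414 with the replicate number as a block, and 82.1% of 418, 88.5% of 183 and 83.3% of 701 without replicates 1, 2 and 3 in turn. The lines differ in genotype throughout, and the labels do not say when the re-watered plants were sampled, so line and stage of recovery were not separated.

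Genes known from seed maturation (glb1, mlg3, esp1, tip3a, tip3b and per-1) were called higher in severe drought in both lines, except tip3b in Han21. Endosperm tissue in the severe-drought samples was tested on 18 endosperm genes. Their median log2 fold change was 0.18 in Han21 (bootstrap SE 0.3) and -0.08 in Ye478 (SE 0.19). Only 3 of them passed the brightness filter, and their median signal in severe drought was 9.1 and 10.2 units, against 1133 and 1572 for glb1, 5904 and 11220 for mlg3 and 2797 and 2205 for esp1. Near the floor a small share of endosperm would be hidden, and embryo tissue was not tested, so tissue and treatment cannot be told apart for these genes. In the other direction, 5 of the 6 genes were lower after re-watering than in severe drought in Han21 and 6 of 6 in Ye478. This comparison uses the severe-drought arrays in which the genes had been picked as high, so it says nothing about a programme that follows the water supply (5 genes in the line with fewer). The exception was tip3b in Han21, which had not been called higher in severe drought, with a log2 fold change of 0.08 and an adjusted p of 0.858. The list of kernel proteins, put together by symbol, was not called under severe drought, with a camera adjusted p of 0.452 in Han21 and 0.785 in Ye478, where its median was -0.41 and its mean 1.52.

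Replicate 1 differed from replicates 2 and 3 in the same way in each of the 8 groups. Independent noise of single arrays was argued against by the correlation of each group's deviation with that of the other groups, which was 0.671 to 0.776 across probe sets. Array scaling was argued against by quantile normalization, after which the first component held 42.1% of the deviations' variance (41.8% before). In all 8 groups 2038 probe sets deviated with the same sign, where 95 would by chance, among them 142 with a gene name. expa1 lay 0.65 higher in replicate 1 on the log2 scale, cesa11 0.56 and gpc3 0.56, while GT1 (-0.59), CDC5 (-0.57) and aos1 (-0.53) lay lower. List medians ranged from -0.1 for ABA synthesis and signalling to 0.2 for tubulins and actin-binding proteins, with 0.18 for fermentation and glycolysis. Of the 7 pairs of control probe sets for RNA integrity, the 3' to 5' ratio of the ubiquitin pair was highest in replicate 1 in 8 of 8 groups, and a glyceraldehyde-3-phosphate dehydrogenase pair in 6. The cyclophilin pair was lowest in 6 of 8 groups, and the other pairs were highest in 2 to 4. A difference in RNA quality or labelling, and a shared day of growth, sampling or hybridisation, stay open, since the labels give no dates, and no biological explanation was tested.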
